A study of Mus musculus with 192 samples.

How the data were processed

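Fetal livers of embryonic day 14.5 mice were dissociated, red cells were lysed, and cells carrying CD3e, CD45R, Ly-6G, CD11b, Ter119, Sca-1, CD16/32 or CD41 were depleted with magnetic beads, per the labels' protocols. The remaining cells were stained for CD117, CD71 and CD24 and with propidium iodide and were sorted singly into plate wells; the gates and the number of animals are not given in the sources used here. Libraries were made by the SmartSeq2 method with Nextera XT tagmentation, which reads whole transcripts, marks neither strand nor molecule, and amplifies by PCR. One plate and 1 sequencing lane held each cell type, so plate, lane and cell type cannot be separated.

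The deposited values are whole-number counts of reads per gene with no normalization, made by the authors with STAR 2.4, featureCounts (version not given) and GRCm38, per the submitters' processing notes. The annotation release, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Reads of near-identical copies, such as the alpha-globin genes or mitochondrial genes with nuclear copies, may therefore be split or dropped. Of 49466 genes, 49326 had a position in the GENCODE M21 annotation of GRCm38, which was used for coordinates, exonic length and gene type. Of 192 cells, 191 columns could be matched to a cell by name (96 BFU-E and 95 CFU-E); the remaining CFU-E cell was not analysed here, and 1 column of per-sample values was not used.

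Cells with at least 100000 counts and 2000 genes were kept, which left out 4 BFU-E and 6 CFU-E cells. Each kept cell was thinned without replacement to 100000 counts (seed 1), so that cells weigh equally and depth does not differ, and thinned counts were summed per cell type to 9200000 and 8900000. Levels are counts per 1000000 counts (CPM) of these sums with exact Poisson intervals. Folds are ratios of CPM with exact conditional binomial intervals, shares carry exact Clopper-Pearson intervals, and log2 folds use log2(CPM + 1). The floor was 3 counts over a group, 0.326 CPM in BFU-E and 0.337 CPM in CFU-E cells, and no fold is given where both groups lie at or under it. With the kept cells of each plate summed, counting error is small for genes above 20 CPM, while differences between animals, plates or lanes have no estimate.

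Cells are not replicates, and each cell type is 1 sample, so no test was made between cell types. The design, the gene lists, the markers and the rule for named genes were fixed before the data were examined. There were 18 pathway lists and 8 marker lists with 488 gene symbols, of which 6 were not analysed here. The pathway lists were sort antigens, erythroid transcription factors, globins, heme synthesis and iron, red cell membrane and maturation, stem and multipotent progenitor, glucocorticoid response and BFU-E renewal, cytokine receptors and STAT5 targets, S phase, G2 and M phase, G1 regulators, ribosome biogenesis and MYC, glycolysis, oxidative phosphorylation, mitochondrially encoded, immediate early and stress, autophagy and apoptosis, and sex-linked genes. The marker lists were megakaryocyte, granulocyte and monocyte, mast cell and basophil, lymphoid, macrophage, hepatocyte, endothelial and stromal, and mature erythroblast. A gene was measured when its mean CPM over the 2 cell types was at least 5. For each list the measured members at least 2-fold higher or lower were counted, and the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile describes these plates only.

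Named genes were the 12 highest and 12 lowest by log2 fold among genes with at least 20 CPM in the higher cell type and a count in at least 50% of its cells. Pseudogenes and predicted genes were left out of that ranking (164 of 5992 eligible genes). Also named were the 3 members with the largest fold and the largest member the other way in each list, the sort antigens, a core panel of erythroid genes and the 3 most abundant markers of each other cell type. Some genes that this rule names are not reported here. The score per cell was the mean log2(CPM + 1) of the measured genes of the erythroid transcription factor, heme and membrane lists minus that of the progenitor list. Within each plate, cells were clustered by Ward's method on 10 principal components of the 1000 most variable genes, with the number of clusters (2 to 5) set by the highest mean silhouette and a silhouette under 0.2 read as no separated clusters. Cells were sorted singly and no doublet caller was run; wells of extreme depth were left out in an alternative.

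Alternatives covered the cell filter, thinning, TMM and median-of-ratios scaling, library sizes without selected genes, the pseudocount, the filter on low levels, cells with odd or even label numbers, the score genes and the clustering settings. Leaving out the CFU-E cells with at least 3 lymphoid markers, alone or with the granulocyte-monocyte-like cells, or the 50 most abundant genes was chosen after seeing the data. The computation of folds was tested on simulated data for the CFU-E over BFU-E comparison. All 100 genes set 2-fold apart and all 100 set 4-fold apart were found in the true direction, with median log2 folds of 0.99 and 1.94, and 99.97% of 9146 unchanged genes lay within 2-fold. Of 200 simulated unchanged lists of 25 genes, 12 fell outside percentiles 2.5 to 97.5. The simulated plates shared the same expression profile apart from the set genes and held no second cell lineage and no plate difference. These rates thus describe the computation and do not carry over to the folds of the real plates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. The TMM factors came from edgeR 4.0.16 and the size factors from DESeq2 1.42.0 in R 4.3.3.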

Results

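Single erythroid progenitors from the liver of embryonic day 14.5 mice of the C57/Bl6J strain were profiled by full-length single-cell RNA sequencing. One 96-well plate held burst-forming units-erythroid (BFU-E), the earliest progenitors committed to the red cell lineage, and the other held colony-forming units-erythroid (CFU-E), their more advanced descendants. The 96 BFU-E wells held a median of 1099619.5 gene-assigned counts (range 6473 to 3864040), and the 95 CFU-E wells used here held a median of 999396 (range 5825 to 2992101). After wells with fewer than 100000 counts were left out, 92 BFU-E and 89 CFU-E cells remained, with medians of 7869.5 and 7789 genes with a count per cell. No label names the animal or pool behind a cell, so each cell type was treated as 1 sample, and every difference below lacks a replicate check and a p-value. Intervals are exact 95% intervals of counting error only, and amplified reads without molecular identifiers are not independent molecules.

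The comparison of CFU-E with BFU-E asks how the transcript content of sorted progenitors differs across this step of red cell development. Transcripts of stem and myeloid progenitors were lower in CFU-E cells, and those of hemoglobin, heme synthesis and the red cell membrane were higher. Cd34, a surface glycoprotein of stem and progenitor cells, was at 622 CPM (95% interval 606 to 638) in BFU-E cells and 0.899 CPM (0.388 to 1.77) in CFU-E cells, 692-fold lower (351 to 1603). Hba-a1, which encodes an alpha chain of hemoglobin, was at 2.5 CPM (1.58 to 3.75) in BFU-E and 499.8 CPM (485 to 515) in CFU-E cells, 199.9-fold higher (133 to 316). Klf1, a transcription factor that drives erythroid genes, was 4.29-fold higher in CFU-E cells (3.998 to 4.61), at 443 against 103 CPM. Epor, the erythropoietin receptor, was 5.21-fold higher (4.81 to 5.67), at 393 against 75.4 CPM. Without the granulocyte-monocyte-like BFU-E cells and 3 lymphoid-marker CFU-E cells described further on, Cd34 stood at 0.930 against 16.6 CPM, Klf1 at 459 against 178 CPM and Epor at 407 against 129.8 CPM. The median log2 fold of the 9445 measured genes was −0.57, and 26.4% of them were higher in CFU-E cells. Scaling by trimmed mean of M values (TMM) or by median-of-ratios size factors moved that median to 0.01 and 0.06. Log2 folds of the 117 named genes with a count rose by a median of 0.51 and 0.57 under these 2 scalings. Folds of single genes near 2 given below thus depend on the scaling, which their counting intervals leave out.

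In GRCm38, Cd34 (ENSMUSG00000016494) lies on chromosome 1 from 194938819 to 194961279. Hba-a1 (ENSMUSG00000069919) lies on chromosome 11 from 32283511 to 32284465, Klf1 (ENSMUSG00000054191) on chromosome 8 from 84901928 to 84905291, and Epor (ENSMUSG00000006235) on chromosome 9 from 21958897 to 21963506. Mpo (ENSMUSG00000009350) lies on chromosome 11 from 87793581 to 87804413, Gata1 (ENSMUSG00000031162) on chromosome X from 7959260 to 7978071, and Car2 (ENSMUSG00000027562) on chromosome 3 from 14886273 to 14900770. All of these are protein-coding genes, and counts were per gene, so no exon or transcript form was resolved.

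Among genes ranked by size, the 12 lowest in CFU-E cells included Mpo, Cd34, Muc13, Plek, Ptprc, Myo1f, Fes, Apoe, Prtn3, Myo1g and Afap1l1. Mpo, the myeloperoxidase of granulocytes and monocytes, was at 1778 CPM (1751 to 1806) in BFU-E cells and had no count in CFU-E cells, which is at least 5275-fold lower against a floor of 3 counts over the group. Muc13, a transmembrane mucin, was at 224 CPM in BFU-E cells and had a single count in CFU-E cells, a ratio of 1991 (357 to 78674). Apoe, the lipid carrier apolipoprotein E, was 116-fold lower (89.9 to 152), at 6.74 against 781 CPM. Plek, the platelet protein pleckstrin, and Myo1f and Myo1g, unconventional myosins of blood cells, were at 204, 149 and 184 CPM in BFU-E cells and at or below 0.899 CPM in CFU-E cells. Fes, a tyrosine kinase of myeloid cells, and Afap1l1 had no count in CFU-E cells and were at least 319-fold and 266-fold lower. Prtn3, the neutrophil serine protease proteinase 3, was at 108 CPM in BFU-E cells and had a single count in CFU-E cells. In the BFU-E cells outside the granulocyte-monocyte-like cluster, Mpo, Myo1f, Fes, Prtn3 and Afap1l1 were lower than over the plate, at 52.8, 28.7, 32.6, 9.25 and 50.4 CPM, and Muc13 and Apoe higher, at 371 and 1183 CPM. Plek and Ptprc stood at 139.6 and 130.6 CPM in these BFU-E cells and had no count in the CFU-E cells without lymphoid markers.

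The 12 highest in CFU-E cells were Hba-a1, Slc39a8, Redrum, Trim10, Cldn13, Tmem56, Slc4a1, Slc26a1, Hbb-bt, Mrap, Trim2 and Sphk1. Slc4a1, the anion exchanger band 3 of the red cell membrane, was at 0.543 CPM in BFU-E and 70.4 CPM in CFU-E cells, a ratio of 129.6 (55.3 to 401). Slc39a8, a zinc and manganese importer, was 121-fold higher (74.2 to 212), at 210.0 CPM, and Redrum, a long noncoding RNA of erythroid cells, was 79.1-fold higher (65.2 to 96.9), at 894 CPM. Cldn13, a claudin, was 73.01-fold higher (48.9 to 114), and Sphk1, which makes sphingosine 1-phosphate, was 40.3-fold higher (30.5 to 54.5). Trim10, a tripartite-motif protein of erythroid cells, was at 78.1 CPM in CFU-E cells and rested on a count of 2 in BFU-E cells, a ratio of 359 (99.1 to 2972), and Trim2, at 43.5 CPM, likewise rested on a count of 2. Mrap, an accessory protein of melanocortin receptors, was 87.7-fold higher (42.3 to 219), and Slc26a1, a sulfate transporter, was 76.8-fold higher (44.7 to 145). Tmem56 was 104-fold higher (52.3 to 241). With the granulocyte-monocyte-like and lymphoid-marker cells left out, Redrum stood at 925 against 19.6 CPM and Sphk1 at 227 against 9.43 CPM. In the BFU-E cells outside the granulocyte-monocyte-like cluster, Slc4a1, Cldn13, Mrap, Slc26a1 and Tmem56 were also higher than over the plate, at 0.943, 4.53, 1.32, 2.26 and 1.51 CPM, which makes their ratios over 1.5 times smaller, and Trim10 and Trim2 had no count.

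Of the 31 measured red cell membrane and maturation genes, 24 were at least 2-fold higher in CFU-E cells and 2 at least 2-fold lower, with a median log2 fold of 2.42 at percentile 100 of 10000 random lists matched on expression. The higher members included Car2, the carbonic anhydrase of red cells, at 6253 against 409 CPM, 15.3-fold (14.8 to 15.8). Epb42 of the membrane skeleton was 33.6-fold higher (24.6 to 46.98). The 2 lower members were Sptbn1, a spectrin chain of non-erythroid cells, at 4.27 against 170.2 CPM, and Car1, a second carbonic anhydrase, which was 11.8-fold lower (10.1 to 13.9). Without the granulocyte-monocyte-like BFU-E cells described further on and 3 CFU-E cells with lymphoid markers, both left out after the data were seen, 21 membrane genes were higher and 2 lower, with a median of 1.71. Of 27 measured genes of heme synthesis and iron, 18 were at least 2-fold higher and 2 lower, with a median of 1.46 at percentile 100, and 17 and 1 with a median of 1.19 without those cells. TMM and median-of-ratios factors each gave 22 higher and 0 lower of 27, so no member was at least 2-fold lower under either. Alad and Fech, the enzymes that form porphobilinogen and insert iron into protoporphyrin, were 15.4-fold (14.5 to 16.3) and 9.93-fold higher (9.41 to 10.5), at 1981 and 1575 CPM in CFU-E cells. Alas2, the first enzyme of erythroid heme synthesis, stood at 29.6 against 5.98 CPM, and Hebp1, a heme-binding protein, at 56.6 against 6.74 CPM. Ireb2, an RNA-binding regulator of iron genes, was 2.47-fold lower (2.17 to 2.82). In the BFU-E cells outside the granulocyte-monocyte-like cluster, Car1, Alad and Hebp1 stood at 392, 208 and 11.5 CPM.

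All 3 measured globins were at least 2-fold higher, with a median of 5.27 (5.77 with genes near the floor set at it) at percentile 100. The beta-chain genes Hbb-bt and Hbb-bs were at 130.1 and 113 CPM in CFU-E cells and at 2.39 and 2.61 CPM in BFU-E cells, and at 1.13 and 4.53 CPM in those outside the granulocyte-monocyte-like cluster. All 24 Hbb-bs counts in BFU-E cells came from 1 of 92 cells, and its log2 fold of 4.98 was 6.88 under a stricter minimum of counts and genes per cell. Hba-a2, nearly identical in sequence to Hba-a1, was at 9.21 CPM in CFU-E cells. How reads shared by such copies were treated is not given, and they may have been split or dropped. The split within each pair and the total level of these globins are thus uncertain. Of the 10 mature erythroblast markers, every one of which also sits in another list, 9 were at least 2-fold higher, with a median of 3.19 at percentile 100. Trim58, a ubiquitin ligase of late erythroblasts, was within counting error, at 5.39 against 6.74 CPM, and stood at 5.58 against 11.5 CPM without the granulocyte-monocyte-like and lymphoid-marker cells.

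Of 19 measured erythroid transcription factors, 6 were at least 2-fold higher and 3 lower, with a median of 0.20 at percentile 99.6. TMM gave 8 higher and 1 lower, and median-of-ratios factors gave 9 and 1. Gata1, the master erythroid regulator, was 2.18-fold higher (2.06 to 2.30), at 437 against 200.4 CPM, and Sox6 was 18.2-fold higher (12.1 to 28.8), at 47.5 against 2.61 CPM. The corepressor Cbfa2t3 was 3.38-fold lower (2.79 to 4.13). Without the granulocyte-monocyte-like and lymphoid-marker cells, 3 factors were higher and 3 lower, the median was −0.13 at percentile 93.2, and Gata1 stood at 452 against 343 CPM.

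None of 29 measured stem and multipotent progenitor genes was at least 2-fold higher in CFU-E cells and 25 were at least 2-fold lower, with a median of −4.24 (−5.00 at the floor) at percentile 0. Gata2, a transcription factor of stem cells and early progenitors, was at 35.9 CPM (32.1 to 39.96) in BFU-E cells and rested on a count of 2 in CFU-E cells, a ratio of 159.6 (43.8 to 1324). Myb, which sustains immature hematopoietic cells, was 6.97-fold lower (6.15 to 7.93), at 31.5 against 219 CPM. Without the granulocyte-monocyte-like and lymphoid-marker cells, 24 of the same 29 were lower, with a median of −3.19; where the 5 CPM minimum was applied again, 18 of 22 measured were lower, with a median of −4.87. Of 13 measured genes of the glucocorticoid response and BFU-E renewal, 10 were lower and 0 higher, with a median of −1.46 (−1.63 at the floor) at percentile 1.43. Nr3c1, the glucocorticoid receptor, was 2.02-fold lower (1.81 to 2.26), Zfp36l2, an RNA-binding protein that maintains BFU-E, 3.77-fold lower (3.03 to 4.74), and Tsc22d3, a glucocorticoid target, 7.63-fold lower (5.59 to 10.7). Nr3c1 had a count in 79.8% of thinned CFU-E and 73.9% of thinned BFU-E cells. Tgfbr2, a receptor for transforming growth factor beta, was at 1.24 against 20.4 CPM, and Dusp1 was within counting error at 7.64 against 5.33 CPM. Of the 12 still measured under TMM 6 were lower, and of the 12 under median-of-ratios factors 5. Once the granulocyte-monocyte-like and lymphoid-marker cells were left out, 9 of the 13 were lower and 1, Dusp1, was higher at 7.67 against 2.08 CPM, and Nr3c1 stood at 54.4 against 167 CPM.

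Of 17 measured cytokine receptors and STAT5 targets, 9 were lower and 2 higher, with a median of −1.23 at percentile 1.67, and TMM gave 5 lower and 3 higher of 16 measured and median-of-ratios factors 4 and 3 of 16. Csf2rb, the shared beta chain of the interleukin-3 receptor, was at 53.3 CPM in BFU-E cells and rested on a count of 3 in CFU-E cells, a ratio of 158 (53.8 to 769). Il6st, the signalling chain of interleukin-6 receptors, was 24.4-fold lower (13.04 to 51.5), and Cxcr4, a chemokine receptor, 10.8-fold lower (5.23 to 25.7). In granulocyte-monocyte-like and other BFU-E cells, Csf2rb stood at 122 and 3.02 CPM, Il6st at 55.1 and 6.98 CPM, and Cxcr4 at 20.3 and 1.89 CPM. Csf2rb and Il6st had no count in the CFU-E cells without lymphoid markers.

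Of 30 measured S phase genes, 5 were at least 2-fold higher and 0 lower, with a median of 0.21 at percentile 96.4, and both TMM and median-of-ratios factors gave 10 higher and 0 lower. Ccne1, the cyclin of S phase entry, was 12.9-fold higher in CFU-E cells (11.7 to 14.3), at 572 against 44.2 CPM. Fen1, the flap endonuclease, was 6.23-fold higher (5.51 to 7.05), and Rrm2, a subunit of ribonucleotide reductase, 4.77-fold higher (4.62 to 4.94). Of 30 measured G2 and M phase genes, 0 were higher and 2 lower, with a median of −0.06 at percentile 83.3 that turned to 0.50 under TMM and 0.56 under median-of-ratios factors, with 6 higher and 0 lower under either, and 1 higher and 2 lower without the granulocyte-monocyte-like and lymphoid-marker cells. The lower members were the mitotic genes Ttk and Kif20b, 2.51-fold (2.21 to 2.86) and 2.46-fold (2.24 to 2.71), and Plk1, a mitotic kinase, stood at 320.5 against 161 CPM. Of 20 measured G1 regulators and CDK inhibitors, 2 were higher and 8 lower, with a median of −0.63 at percentile 30.8, which was −0.01 with 4 higher and 5 lower of 19 measured under TMM and 0.05 with the same counts under median-of-ratios factors. Cdk6, a kinase of G1 progression, was 5.63-fold lower (5.32 to 5.96), at 161 against 907 CPM, and Ccnd2, a D-type cyclin, 3.15-fold lower (2.93 to 3.38). Ccnd1 and Ccng2 were lower at 1.12 against 38.2 CPM and 0.787 against 12.9 CPM, and Btg2, an antiproliferative gene, was 4.64-fold higher (3.72 to 5.84). With the granulocyte-monocyte-like and lymphoid-marker cells left out, Ccnd1 stood at 0.581 against 6.98 CPM, Ccng2 at 0.233 against 1.70 CPM and Btg2 at 51.05 against 3.77 CPM. Cdkn1b, which encodes the inhibitor p27, stood at 8.09 against 10.3 CPM, within counting error.

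Of 28 measured genes of ribosome biogenesis and MYC, 0 were higher and 1 lower, with a median of −0.25 at percentile 41.3 that turned to 0.33 under TMM and 0.38 under median-of-ratios factors, with 4 higher and 0 lower of 27 measured under either, and 0 higher and 3 lower without the granulocyte-monocyte-like and lymphoid-marker cells. Myc itself was 1.91-fold lower (1.82 to 1.9996), Gar1 was at 2.70 against 7.72 CPM, Rrp9 at 58.4 against 115 CPM, and Npm1, nucleophosmin, at 7412 against 4049.5 CPM. Of 18 measured glycolysis genes, 2 were higher and 5 lower, with a median of −0.50 at percentile 7.13, which turned to 0.30 with 4 higher and 3 lower of 17 measured under TMM and to 0.36 with 6 and 3 of 17 under median-of-ratios factors. Pklr, which encodes the red cell pyruvate kinase, was 11.97-fold higher in CFU-E cells (10.4 to 13.8), whereas Hk2, a hexokinase, was 6.71-fold lower (5.36 to 8.47) and Ldhb 19.5-fold lower (8.10 to 61.5). Once the granulocyte-monocyte-like and lymphoid-marker cells were left out, Pklr stood at 285 against 38.3 CPM, Hk2 at 5.23 against 24.2 CPM and Ldhb at 0.581 against 4.91 CPM. Of 34 measured nuclear-encoded oxidative phosphorylation genes, 0 were higher and 5 lower, with a median of −0.19 at percentile 67.2 that turned to 0.38 under TMM and 0.43 under median-of-ratios factors, with 6 higher and 1 lower under either. Ndufa2, Cox6c and Cox7a2 were 4.43-fold (3.50 to 5.66), 2.91-fold (2.54 to 3.35) and 2.88-fold lower (2.38 to 3.50), and Atp5b, a subunit of ATP synthase, stood at 4844 against 2460 CPM. Of 9 measured mitochondrially encoded genes, 1 was higher and 3 lower, with a median of −0.10 at percentile 54.1, which turned to 0.47 under TMM and 0.53 under median-of-ratios factors, with 2 higher and 1 lower under either. The lowest were mt-Nd6, at 60 against 209.9 CPM, and mt-Nd3, at 12.7 against 32.2 CPM, and mt-Atp6 was higher at 16.7 against 6.52 CPM. Near-copies of mitochondrial genes lie in the nuclear genome, mt-Nd6 is transcribed from the opposite strand to its neighbours and strand use in counting is not given, so these levels are uncertain. Levels of mt-Co2 and mt-Co3 were 2.72 and 5.11 CPM in BFU-E and 2.36 and 4.04 CPM in CFU-E cells. For mt-Co1 they were 7932 and 11927 CPM. Reads shared with near-copies may thus have been dropped, which was not tested, and the mt-Atp6 difference may rest on the remaining reads.

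Of 17 measured autophagy and apoptosis genes, 2 were higher and 6 lower, with a median of −0.35 at percentile 74.4, which turned to 0.21 under TMM and 0.27 under median-of-ratios factors, with 2 higher and 3 lower under either. Bcl2, an inhibitor of cell death, was 15.6-fold lower (9.72 to 26.8) and Pmaip1, a promoter of cell death, 18.5-fold lower (8.74 to 46.9), whereas Bcl2l11, another promoter, was 3.77-fold higher (2.90 to 4.95). Bcl2 stood at 61.5 CPM in the granulocyte-monocyte-like BFU-E cells and 9.62 CPM in the other BFU-E cells, and Pmaip1 at 32.6 and 1.32 CPM. Without the granulocyte-monocyte-like and lymphoid-marker cells 1 gene of the list was higher and 4 lower. Of the 5 measured immediate early and dissociation stress genes, 2 were higher and 1 lower, with a median of 0.03 at percentile 76.5, and 2 were higher and 0 lower of the 4 measured under TMM and median-of-ratios factors. The chaperones Hspa8 and Dnajb1 were 3.25-fold (3.22 to 3.29) and 2.24-fold higher (2.04 to 2.47), and Jun, a subunit of the AP-1 transcription factor, stood at 2.36 against 8.37 CPM. Without the granulocyte-monocyte-like and lymphoid-marker cells Jun was at 1.63 against 1.89 CPM, and 2 genes of the list were higher and 0 lower, with a median of −0.14.

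**Figure D1:**
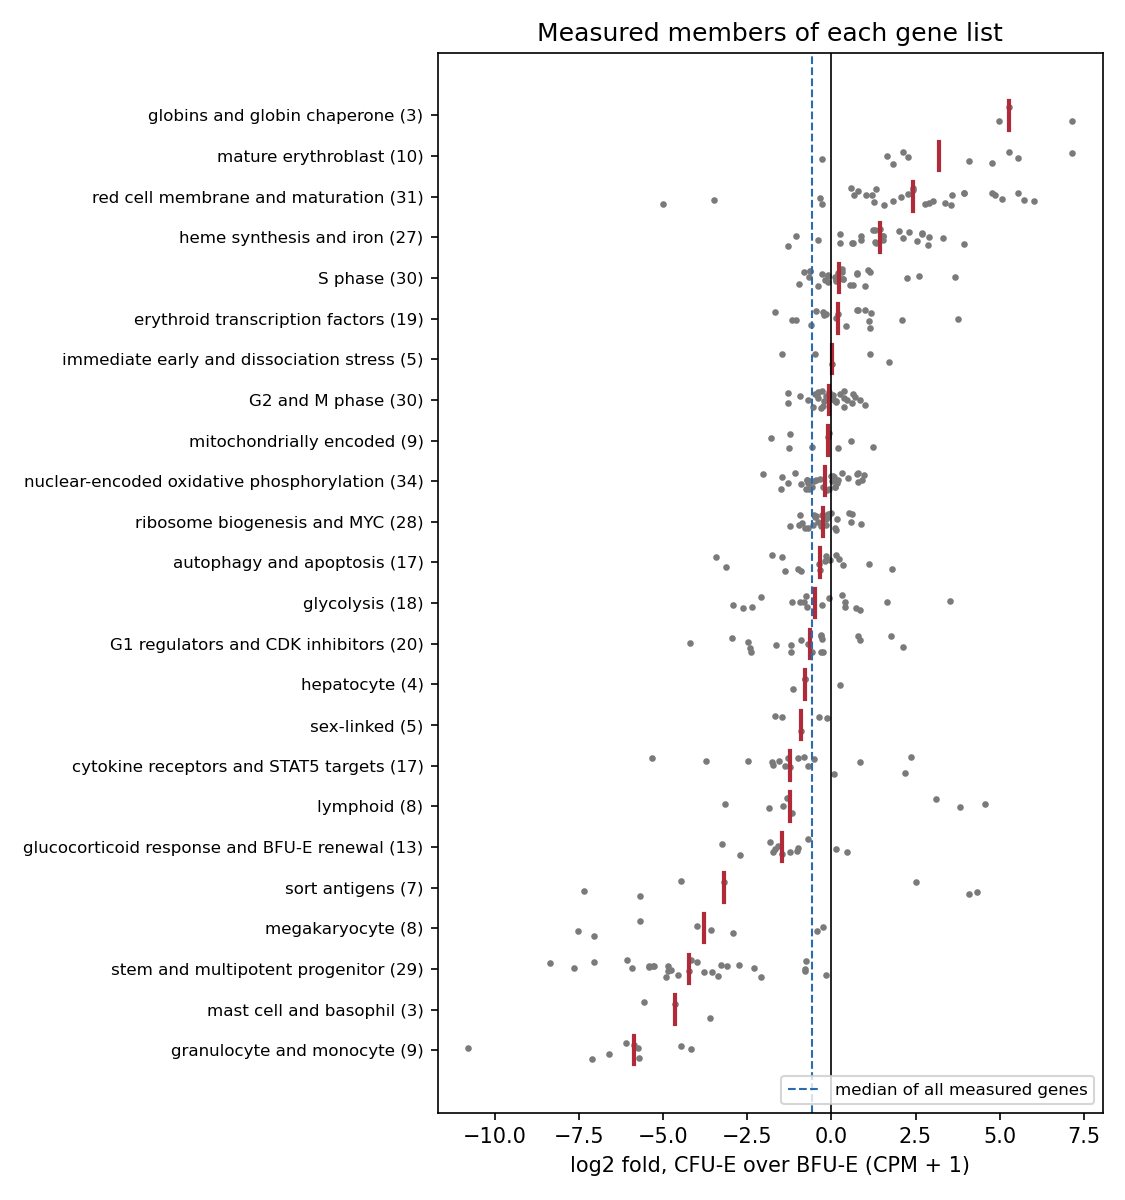
Log2 fold of CFU-E over BFU-E cells, from CPM + 1 of summed thinned counts, on the horizontal axis for every measured member (grey points, vertical spread for legibility only) of each gene list with at least 3 measured members, whose number stands in brackets. Red bars are list medians, from −5.88 for granulocyte and monocyte markers to 5.27 for globins, and the dashed line is the median of all measured genes, −0.57; bars between that line and 0 turn positive under TMM scaling for the G2 and M phase, mitochondrially encoded, oxidative phosphorylation, ribosome, autophagy and glycolysis lists.

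Genes of antigens used in the depletion or the sort were read as a check only, since a gene used to choose cells is no finding between them. Of 7 measured, 3 were higher and 4 lower in CFU-E cells, with a median of −3.19 at percentile 0. The higher members included Tfrc (CD71), at 1362 against 237 CPM, and Cd24a, at 2495 against 122 CPM. Lower were Kit (CD117), at 66.1 against 611 CPM, Ptprc, at 0.899 against 313 CPM, Itga2b (CD41), at 1.91 against 149 CPM, and Fcgr3 (CD16), with no count against 21.2 CPM. Itgam (CD11b) and Fcgr2b (CD32) had no count in CFU-E cells and stood at 8.70 and 8.59 CPM in BFU-E cells. In the BFU-E cells outside the granulocyte-monocyte-like cluster, Cd24a, Itga2b, Fcgr3 and Fcgr2b stood at 72.6, 241, 4.72 and 2.08 CPM, and Itgam had no count. Ly6a (Sca-1) had 4 counts in BFU-E and 0 in CFU-E cells, and Cd3e and Ly6g had 0 in both.

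Within the BFU-E plate, cells formed 2 clusters with a mean silhouette of 0.33. One held 39 of 92 cells, 42.4% (exact interval 32.1 to 53.1), and was led by Flt3, Tifab, Ncf1, Lsp1, Gria3, Emb and Csf1r. It was called granulocyte-monocyte-like as the cluster with the higher summed level of granulocyte and monocyte markers per cell. All 9 measured markers of that list were at least 2-fold higher in it than in the other cluster. That follows in part from this choice and is no test of the name. Also at least 2-fold higher in it were 6 of 8 measured lymphoid and 2 of 3 mast cell and basophil markers, with 0 lower. So were the 1 measured macrophage marker and the 2 measured endothelial and stromal markers. Of 8 measured megakaryocyte markers, 2 were higher and 4 lower in this cluster. Flt3 and Ighm, also found on multipotent and lymphoid progenitors, were among its leading genes. Leading genes of the other 53 cells included Gm15915, Mfsd2b, Ermap, Car1, Slc38a5, Samd14 and Klf1. Median counts were 1119889 and 1121648, so depth did not separate them. Granulocyte and monocyte markers summed to 5569 CPM (5495 to 5644) in the 39 cells, 97.9 CPM (89.7 to 107) in the other 53 and 1.69 CPM (0.943 to 2.78) in CFU-E cells. The lineage depletion named in the labels targets Ly-6G, CD11b and CD16/32 and would remove myeloid cells that carry these antigens. The sort gates are not given in the sources used here. In CFU-E cells the highest mean silhouette was 0.15, under the 0.2 set for describing clusters, and 0.0819 to 0.223 under other clustering settings, with the value above 0.2 from 5 principal components. Of the 3 CFU-E clusters at that silhouette of 0.15, 1 held only the 3 cells with lymphoid markers.

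Because Mpo and Cd34 ranked lowest through these 39 cells, levels were also taken by set. Mpo was at 4123 CPM in the granulocyte-monocyte-like cells and 52.8 CPM in the other BFU-E cells, and Cd34 at 1444 and 16.6 CPM. Muc13 and Apoe ran the other way, at 23.6 and 371 CPM and at 236 and 1183 CPM. Gata1 stood at 6.92 CPM in the granulocyte-monocyte-like cells, 343 CPM in the other BFU-E cells and 452 CPM in the CFU-E cells without lymphoid markers, and Klf1 at 2.05, 178 and 459 CPM in the same order. Car1 was at 2.05, 392 and 19.9 CPM, so that its level was highest in the other BFU-E cells, and Alad was at 21.3, 208 and 2048 CPM. Of 117 named genes with a count, the fold of CPM + 1 moved by over 1.5 times in 52 when the granulocyte-monocyte-like and lymphoid-marker cells were left out. Some low CFU-E levels rested on few cells: the counts of Cd34, Ptprc, Myo1g, Il6st and Ccng2 came from 2 cells each and those of Csf1r, Hdc and Ldhb from 1 cell each. The sets were drawn from the expression of such genes, so these levels describe the sets and do not test them.

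**Figure D2:**
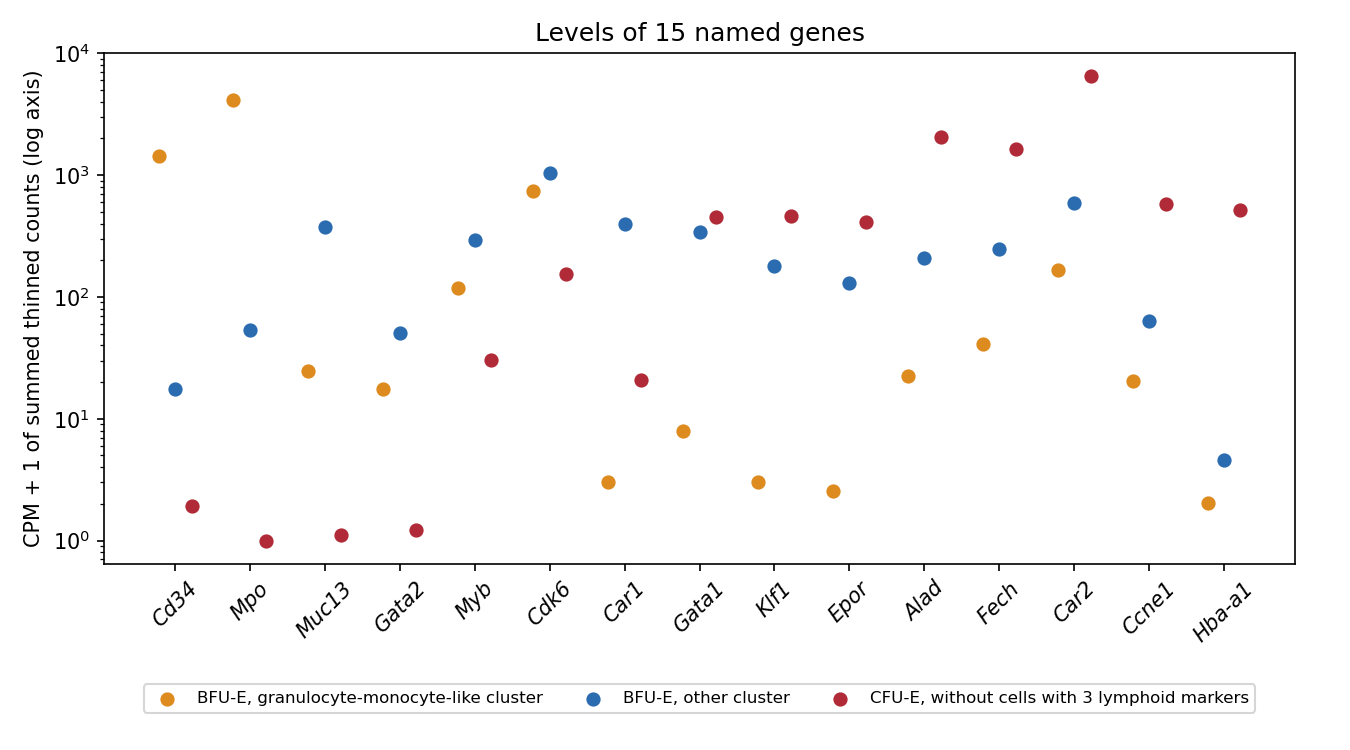
CPM plus 1 of summed thinned counts, on a log axis, of 15 named genes in the 39 granulocyte-monocyte-like BFU-E cells (orange), the other 53 BFU-E cells (blue) and the 86 CFU-E cells without lymphoid markers (red). Cd34 and Mpo were highest in the orange set, Muc13, Gata2, Myb, Cdk6 and Car1 in the blue set, and Gata1, Klf1, Epor, Alad, Fech, Car2, Ccne1 and Hba-a1 in the red set.

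Per cell, the mean of 77 erythroid genes minus that of 29 progenitor genes, on the log2 scale, had a median of −0.46 (SD between cells 1.77) in 92 BFU-E cells and 5.27 (SD 1.08) in 89 CFU-E cells, a difference of 5.73. The CFU-E cell was the higher in 98.5% of all pairs of 1 cell from each plate. The lowest 10% of CFU-E cells ended at 4.65, and 0 of 92 BFU-E cells lay above it, which allows a share of up to 3.93% by the exact interval; 3 cells would be 3.26%. The 3 CFU-E cells with lymphoid markers were the only CFU-E cells below the highest BFU-E cell, at 3.50. Within the BFU-E plate the median was −1.90 in the granulocyte-monocyte-like cells and 0.85 in the others.

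**Figure D3:**
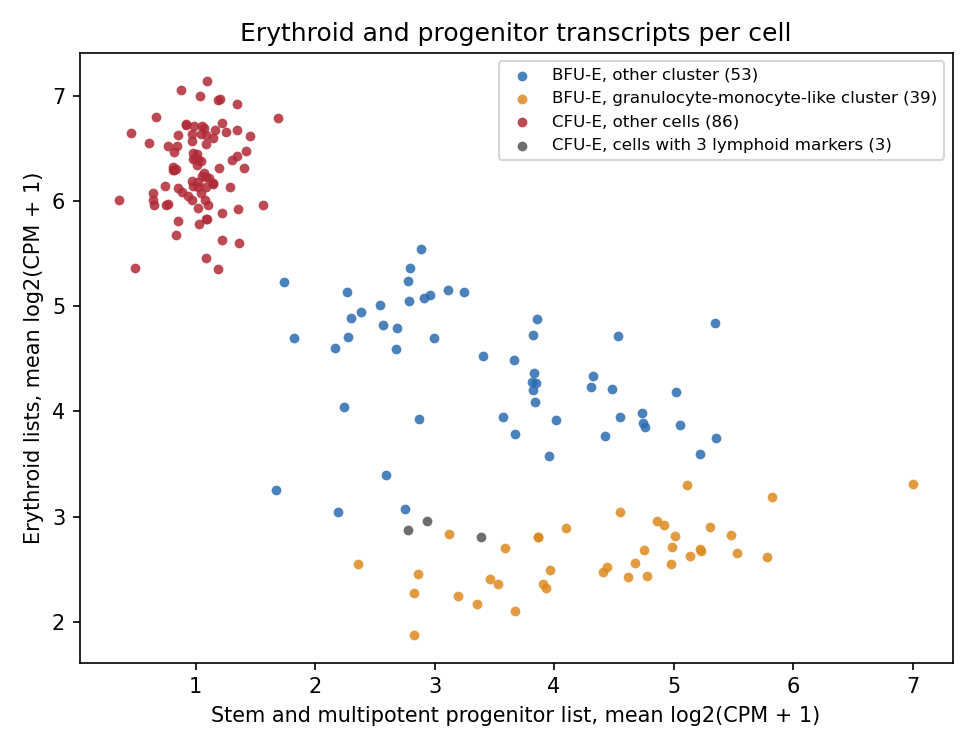
Each point is 1 cell, with the mean log2(CPM + 1) of the stem and multipotent progenitor list on the horizontal axis and that of the erythroid lists on the vertical axis, and colours give the cell sets with their numbers. The 86 CFU-E cells without lymphoid markers lie between 5.35 and 7.15 on the vertical axis, and the 39 granulocyte-monocyte-like BFU-E cells between 1.87 and 3.31.

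Markers of granulocytes and monocytes, megakaryocytes and mast cells were lower in CFU-E cells, whereas lymphoid markers summed to 114 CPM in CFU-E and 98.04 CPM in BFU-E cells. Of the 1011 lymphoid marker counts in CFU-E cells, 966 came from the 3 lymphoid-marker cells. Lymphoid markers summed to 5.23 CPM in the other 86 CFU-E cells and to 14.5 CPM in BFU-E cells outside the granulocyte-monocyte-like cluster. All 9 measured granulocyte and monocyte markers were at least 2-fold lower, with a median of −5.88 (−7.60 at the floor) at percentile 0, and 6 of these 9 were so without the granulocyte-monocyte-like and lymphoid-marker cells. Csf1r, the receptor of macrophage colony-stimulating factor, stood at 200.2 CPM in BFU-E and 0.449 CPM in CFU-E cells, and at 2.08 CPM in BFU-E cells outside the granulocyte-monocyte-like cluster. Spi1 and Fcgr3 of this list are also in the progenitor and sort antigen lists. Of 8 measured megakaryocyte markers, 6 were lower and 0 higher, with a median of −3.78 (−5.05 at the floor) at percentile 0, and their summed level was 585 CPM in BFU-E and 27.98 CPM in CFU-E cells. Members of this list, Cd9 and Itga2b among them, sit in other lists too. The megakaryocyte sum was 500.3 CPM in granulocyte-monocyte-like and 648 CPM in other BFU-E cells. All 3 measured mast cell and basophil markers were lower, with a median of −4.66 (−6.31 at the floor) at percentile 0.225. Cpa3, a mast cell carboxypeptidase, had no count in CFU-E cells, and Hdc, which makes histamine, was at 0.449 against 35.8 CPM; in the other BFU-E cells Cpa3 stood at 4.72 CPM and Hdc at 18.1 CPM. Srgn, a proteoglycan of secretory granules, was 12.7-fold lower (10.8 to 15.1). The 2 measured endothelial and stromal markers, Pecam1 and Pdgfrb, were both lower, with a median of −5.36 (−6.96 at the floor) at percentile 0.03, and their levels in granulocyte-monocyte-like and other BFU-E cells were 130.3 and 20.9 CPM for Pecam1 and 72.1 and 7.55 CPM for Pdgfrb. Of the macrophage markers only Cd68 was measured, at 16.3 CPM in BFU-E and 2.47 CPM in CFU-E cells, a log2 fold of −2.32 (−2.72 at the floor) at percentile 20.02; it stood at 35.1 and 2.45 CPM in the granulocyte-monocyte-like and other BFU-E cells.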

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

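The leave-outs of lymphoid-marker cells, alone or with granulocyte-monocyte-like cells, and of the 50 most abundant genes were chosen after seeing the data. Under all 20 alternative settings run on the lists, the counts of higher red cell membrane genes (21 to 27) and heme and iron genes (16 to 22) and of lower stem and progenitor genes (18 to 26) stayed within 1.5 times their values, and their medians kept their direction. The score gave 96.9 to 100% of cell pairs with the CFU-E cell higher in 15 settings, with 0% of BFU-E cells above the lowest 10% of CFU-E cells in each; its median difference of 5.73 was 3.44 and 8.11 with 10 and 0.1 CPM in place of 1, 2.54 for the erythroid lists alone and 4.88 to 6.56 in the other 11 settings. The granulocyte-monocyte-like cluster held 38 or 39 cells in 5 clustering settings. The highest CFU-E silhouette passed 0.2 with 5 principal components, at 0.223. The median log2 fold of all measured genes reversed from −0.57 to 0.0082 with TMM and 0.064 with median-of-ratios factors, as those factors centre it. Erythroid transcription factors at least 2-fold higher numbered 3 in place of 6 with cells thinned to 30000 counts, and the list's median reversed from 0.20 to −0.013 with a minimum of 20 CPM; the cause was not tested. Without the granulocyte-monocyte-like BFU-E and lymphoid-marker CFU-E cells, 3 factors were higher and the list's median was −0.13. Granulocyte and monocyte markers lower then numbered 2 where the 5 CPM minimum was applied again. Without the same cells Rag2 went from −1.32 to 0.16, at 0 CPM in BFU-E and 0.116 CPM in CFU-E cells. Both levels lie under the floor, so no direction can be read from them. Itgam, with no count left in either set, went from −3.28 to 0. Without the lymphoid-marker cells alone, Ebf1 reversed from 3.12 to −1.12. With cells of odd label numbers only, Rag2, Cd79b and Fgb reversed to 0.92, 0.018 and 1.06, and with even numbers only Ebf1 reversed to −1.98. In CFU-E cells Ebf1, Rag2 and Cd79b were found mostly in the 3 lymphoid-marker cells, and the cause for Fgb was not tested. All 103 named genes at least 2-fold apart kept their direction in every other setting run on genes. Fewer stayed at least 2-fold apart: 86 with 10 CPM in place of 1, 90 with median-of-ratios factors, 91 with TMM, 92 without the granulocyte-monocyte-like and lymphoid-marker cells, 95 with odd label numbers, and at least 99 in the others. A limit of 20% on mitochondrially encoded counts removed no cell and tests nothing. The median share of such counts per kept cell was 3.49% in BFU-E and 4.93% in CFU-E cells. The 10 most abundant genes of each kept cell took a median of 9.99% of its counts in BFU-E and 18.1% in CFU-E cells. These measures thus differed along with cell type. No paired analysis was possible because each plate is 1 sample, the label numbers name wells and no model was fitted. Depth limits genes near the floor, whose ratios carry wide intervals.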

Other observations

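The sets of cells left out and the tests of the 3 patterns weighed below were chosen after the data were seen, that of the most abundant genes before its own result was known. The lymphoid list held 3 higher and 5 lower genes of 8 measured in CFU-E cells, with a median log2 fold of −1.25 (−1.34 at the floor) at percentile 30.4, against 4 higher and 1 lower and a median of 0.89 under TMM and 0.94 under median-of-ratios factors. Of the same 8, 1 was higher and 1 lower, with a median of 0.23, without the granulocyte-monocyte-like and lymphoid-marker cells. Without the lymphoid-marker cells alone, 0 were higher and 5 lower of 5 measured, with a median of −3.98. The higher members included Igll1 and Ebf1, genes of B cell precursors, and their counts in CFU-E cells came mostly from 3 of 89 CFU-E cells (3.37%, exact interval 0.701 to 9.54) in which at least 3 lymphoid markers had a count. In those 3 cells Ebf1, Cd79b, Igll1 and Rag2 stood at 777, 440.0, 383 and 177 CPM. In the other 86 CFU-E cells none of these 4 exceeded 0.465 CPM, and the summed lymphoid markers were at 5.23 CPM against 3220 CPM. The 3 cells held 3.33 CPM of Gata1, while Cd24a stood at 2213 CPM and Tfrc at 453 CPM. Their median depth was 443001 counts against 1011596 in the other CFU-E cells. In BFU-E cells lymphoid markers summed to 212 CPM in the granulocyte-monocyte-like cells and 14.5 CPM in the others, with Cd52 at 25.6 and 0.377 CPM. At least 3 lymphoid markers had a count in 9 of 92 BFU-E cells (9.78%, exact interval 4.57 to 17.8). These were 9 of the 39 granulocyte-monocyte-like cells and 0 of the other 53.

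Of the 4 measured hepatocyte markers, Alb and Afp were found in most cells of both plates. Fgb had a count in 9.78% of thinned BFU-E and 8.99% of thinned CFU-E cells, and Ahsg in 15.2% and 13.5%. Alb, serum albumin, had a count in 63.04% of thinned BFU-E cells (75% unthinned) and 64.05% of thinned CFU-E cells (85.4% unthinned), at 89.7 and 51.01 CPM, and Afp, alpha-fetoprotein, stood at 87.7 and 105 CPM. Of the 4 measured hepatocyte markers 0 were higher and 1 lower in CFU-E cells, the last being Fgb at 3.03 against 7.93 CPM, with a median of −0.80 (−0.88 at the floor) at percentile 42.8, and 2 were lower without the granulocyte-monocyte-like and lymphoid-marker cells. TMM and median-of-ratios factors each gave 0 higher and 0 lower of these 4. Of 5 measured sex-linked genes, 2 were lower and 0 higher in CFU-E cells, with a median of −0.89 (−0.91 at the floor) at percentile 21.5. TMM and median-of-ratios factors each gave 1 lower and 0 higher, with medians of −0.33 and −0.28. Without the granulocyte-monocyte-like and lymphoid-marker cells 3 were lower and 0 higher, with a median of −1.27. Xist, the RNA of the inactive X chromosome, was 3.25-fold lower (3.02 to 3.50), at 104 against 337 CPM, and Kdm5d, on the Y chromosome, 2.95-fold lower (2.31 to 3.79). At 10 CPM or more per cell, 38 BFU-E cells held Xist alone, 51 Y-linked transcripts alone, 2 both and 1 neither, and among CFU-E cells the numbers were 45, 40, 3 and 1. Xist was thus at a lower level in CFU-E cells although more of them held it. The mitochondrial ribosomal RNA mt-Rnr2 was 2.36-fold higher in CFU-E cells (2.34 to 2.37), at 27411 against 11632 CPM, and Eef1a1, the elongation factor of translation, 2.11-fold higher (2.09 to 2.12), at 31090 against 14759 CPM.

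The first pattern weighed is that erythroid lists were higher and the progenitor list lower in CFU-E cells. Granulocyte-monocyte-like BFU-E cells could lower the erythroid mean of their plate, but without them and the 3 lymphoid-marker CFU-E cells the red cell membrane median was 1.71 (matched random lists −0.65 to 0.015) and the progenitor median −3.19 (−0.94 to −0.16), which argues against them as the whole cause. For erythroid transcription factors the median without both sets was −0.13, inside the random range of −0.94 to 0.00, and 0.19 without the lymphoid-marker cells alone, so their higher median is consistent with the makeup of the BFU-E plate. A shift that depends on expression level is argued against by percentile 100 of the membrane list among expression-matched lists. A plate or lane difference cannot be told apart from cell type, since 0 cell types were sequenced in more than 1 lane, and the difference between BFU-E and CFU-E as stages stays open beside it.

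The second pattern is the negative median over all measured genes, −0.57. The 50 most abundant genes took 18.5% of counts in BFU-E and 30.4% in CFU-E cells, and leaving them out of both library sizes moved the median to −0.36, so they may account for part of it, while over 50% of its size was kept. Without the granulocyte-monocyte-like and lymphoid-marker cells it was −0.54 (−0.58 without the latter alone), and in 5 classes of genes by exonic length it ran from −0.45 to −0.78, which argues against those cells and gene length as the whole cause. By expression level the medians of 5 such classes went from −1.07 in the lowest to −0.16 in the highest. RNA content per cell was not measured. An equal change of all transcripts would cancel in CPM at equal depth and would not shift the median over all measured genes. A change confined to some transcripts stays open.

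The third pattern is the granulocyte-monocyte-like cells in the BFU-E plate. Wells that held an erythroid and a granulocyte-monocyte-like cell would carry much of the erythroid level. In the 39 cells, Gata1, Klf1 and Epor summed to 1.62% (1.16 to 2.20) of the level in the other BFU-E cells. These genes also separate the clusters, so wells with 2 such cells would tend to fall in the other cluster. The low level thus shows that the 39 wells held little of these transcripts and does not test for wells with 2 cells in the plate. Among those other 53 cells, 14 had a count in at least 3 granulocyte and monocyte markers. Of the 53, 21 held Xist alone, 31 Y-linked transcripts alone, 1 both and 0 neither. A well with a female and a male cell would hold both. These numbers thus argue against 2 cells of unlike sex in most of the 14 wells. Wells with 2 cells of the same sex would not show in this way, so whether some of the 14 held 2 cells stays open. Cells of another lineage inside the BFU-E gate are a possible explanation. It cannot be told apart from a mixed state of early progenitors with little Gata1, Klf1 and Epor. Fcgr3, an antigen gene of the depletion, stood at 43.6 CPM in the 39 cells, and no reference population was sequenced. The 1.62% argues against a state in which these 39 wells carried Gata1, Klf1 and Epor at the level of the other BFU-E cells. Of 19 measured erythroid transcription factors, 12 lay within 2-fold between the 2 clusters, and 7 were at least 2-fold lower in the 39 cells and 0 higher. The most abundant markers of the 39 cells were Mpo at 4123 CPM and Csf1r at 469 CPM.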
